A study of Macaca fascicularis with 36 samples.

How the data were processed

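Bulk RNA from the frontal cortex of 12 cynomolgus monkeys (Macaca fascicularis) was sequenced in 36 libraries, 3 per animal. Per the labels, the animals received an intrathecal injection of Para09, an agonist antibody against human TREM2, at 50 or 200 mg/kg, or of anti-gD, an isotype control antibody, at 200 mg/kg, and the brain was sampled on day 2. How doses per kg apply to that route is not stated there. RNA was extracted with a kit for lipid-rich tissue and a DNase step, per the labels' protocols. Each group held 4 animals. The 3 libraries of an animal carry the letters A, B and C, whose meaning is not given in the sources used here. The sample identifiers in the titles fall into 2 separate runs of numbers, called the first series (16 libraries) and the second series (20 libraries) below. The first series held the B library of every animal and all libraries of control animal 1504 and of animal 5501 at 200 mg/kg, and the second series held the A and C libraries of the other 10 animals. The first series therefore held 6 control libraries, 4 at 50 mg/kg and 6 at 200 mg/kg.

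The deposited tables hold, for each library, a whole-number read count, an exonic width and an RPKM for 28623 genes, per the file headers. GSNAP is the aligner named in the submitters' processing notes, without a version. The genome build, the annotation release, the treatment of strand and of reads that match several places, and the library kit are not given in the sources used here, so genes that overlap or share sequence with close copies may have exchanged counts. The deposited RPKM values equal the count per kilobase of the width scaled to a total that is larger than the sum of the counts. In the first series the counts made up a mean of 57.1% of that total, and in the second series 59.5%. The counts as deposited were used in every test, and the RPKM values were used only to recover those totals. In all, 4650 genes had no count in any library.

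The genes carry Ensembl-type identifiers, and the files do not pair them with gene names. The reference table of 40596 genes (assembly T2T-MFA8v1.1) matched 0 of the 28623 identifiers, because 0 of its genes carry an Ensembl identifier. The 37 gene lists fixed before the data were examined, which covered microglia, other cell types, interferon response and related pathways, could not be applied, and no result is given for any of them, for TREM2 or for cell type markers. The rule for named genes, also fixed before the data were examined, required a symbol. It was replaced, after the files were read, by the 2 genes higher and the 2 genes lower with the smallest p at 200 mg/kg against anti-gD among genes with a mean CPM (library-size-scaled count) of at least 1. These 4 genes were picked for their small p, so their own p-values and fold changes are biased toward large effects.

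The animal was the replicate. Counts were summed over the 3 libraries of an animal and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM normalisation, filterByExpr, all 12 animals in a single fit), which left 17360 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were derived from the fold change and the F statistic. Log2 CPM values used a prior count of 2. For single genes an exact two-sided permutation test on log2 CPM of 4 animals against 4 was added, and its smallest possible p is 0.0286. Alternatives fixed before the data were examined were RLE size factors, DESeq2 1.42.0, no low-count filter, a mean CPM of at least 1, only the compared groups, single letters, equal weight per library (limma 3.58.1, trend), a library-level model, 1 surrogate variable (sva 3.50.0) and each animal left out. The library-level model was limma voom on all 36 libraries, with letter and series as covariates and the animal as a random block, and it tested 15928 genes with a within-animal correlation of 0.273. Fits within the second series, without animals 1504 and 5501, with an indicator for them, without library 5501B and on series-adjusted animal means, the overlap of the doses in the library-level model, the genes of smallest p in simulated unchanged groups, named genes without each animal at 50 mg/kg and between the doses, and all alternatives of that model itself, were chosen after seeing the data.

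Libraries held 15.1 to 37.0 M counts, where M stands for the SI prefix mega. The 36 pairs of libraries from the same animal differed by 8.70 to 184 times the counting noise (chi-square per degree of freedom), and the 630 pairs among all libraries by 8.70 to 289 times, so no pair differed by as little as counting noise. Both models were tested on simulated data with 200 genes changed by known folds. In the edgeR fit of 200 mg/kg against anti-gD, 10.4% of genes changed 1.5-fold, 53.8% of those changed 2-fold and 84.8% of those changed 4-fold were recovered, among 17310 genes. At 50 mg/kg against anti-gD these shares were 7.46%, 48.5% and 84.8%, and for 200 against 50 mg/kg they were 14.9%, 53.7% and 92.4% among 17312 genes. In the library-level model at 200 mg/kg the shares were 46.3%, 78.8% and 92.4% among 15916 genes, but 23.0% of its calls were false, above the nominal 5%. In 3 simulations without change it called 1, 2 and 3 genes. Comparisons of both doses with the same 4 controls were set beside simulated unchanged groups.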

Results

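The frontal cortex of 12 cynomolgus monkeys was profiled by bulk RNA sequencing on day 2 after intrathecal injection of Para09, an agonist antibody against TREM2, or of the isotype control antibody anti-gD. TREM2 is a receptor of microglia, the resident macrophages of the brain. Each of the 3 groups (anti-gD at 200 mg/kg, Para09 at 50 mg/kg and Para09 at 200 mg/kg) held 4 animals with 3 libraries each. Route and doses are given as labelled, and how doses per kg apply to an intrathecal injection is not given in the sources used here. Total counts per library averaged 21.3 M ± 3.23 with anti-gD, 22.9 M ± 5.26 at 50 mg/kg and 21.6 M ± 2.78 at 200 mg/kg (SD, n = 12 libraries). Summed per animal, totals ranged from 54.7 to 80.3 M. Genes are given by their identifiers because the files do not pair them with names.

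The comparison of Para09 at 200 mg/kg with anti-gD asked which transcripts differ at the higher dose. ENSMFAG00000042945, an abundant transcript, stood at 2675 CPM ± 253 at 200 mg/kg and at 1201 CPM ± 175 with anti-gD (SD, n = 4 animals), a log2 fold change of 1.16 (SE 0.17). ENSMFAG00000037072 stood at 4.52 CPM ± 3.81 against 0.460 CPM ± 0.103 (SD, n = 4 animals), a log2 fold change of 3.29 (SE 0.52). Its spread at 200 mg/kg came largely from animal 5503, at 9.95 CPM, while the other 3 animals lay between 1.81 and 4.41 CPM, and without animal 5503 the log2 fold change was 2.54; in letter A alone it was 3.90. Lower levels were seen for ENSMFAG00000044843, at 2.01 CPM ± 0.397 against 4.60 CPM ± 0.738 (log2 fold change -1.20, SE 0.19), and for ENSMFAG00000035883, at 17.1 CPM ± 2.56 against 30.02 CPM ± 3.17 (log2 fold change -0.81, SE 0.19; SD, n = 4 animals). For each of these 4 genes the 4 treated animals lay entirely outside the range of the 4 control animals, an arrangement with an exact two-sided permutation p of 0.0286, the smallest this design can give; the genes were chosen for a small p on the same animals.

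None of these differences passed the edgeR test across all genes. In the edgeR quasi-likelihood test on animal sums, 0 of 17360 genes were called at 200 mg/kg, and the adjusted p was 0.237 for ENSMFAG00000042945, ENSMFAG00000037072 and ENSMFAG00000044843 and 1 for ENSMFAG00000035883. At an unadjusted p under 0.05 there were 691 genes, where evenly spread p-values give 868 with no gene changed. Other splits of the same animals gave a median of 711.5, and 19 of 35 splits, the real one included, gave as many. The 20 splits that part animals 1504 and 5501, the real split included, gave a median of 375, and 4 of them gave as many. For the real groups the count was 1050 without control animal 1502, 1177 without control animal 1504 and 1092 without animal 5501. Over the alternatives other than leaving out 1 animal it ran from 335 to 2158. The highest came from the second series alone, which lacks animals 1504 and 5501. DESeq2 called 14 genes, 13 higher and 1 lower, and the library-level limma voom model called 16. Both called ENSMFAG00000042945, ENSMFAG00000037072 and ENSMFAG00000044843 (DESeq2 adjusted p 2.83e-06, 3.8e-07 and 6.75e-06), and neither called ENSMFAG00000035883 (DESeq2 adjusted p 0.0743). Within the first series (letter B, all 12 animals) and within the second series (10 animals), edgeR called 0 genes each. In those within-series fits the log2 fold change was 1.06 and 1.09 for ENSMFAG00000042945, 3.05 and 3.63 for ENSMFAG00000037072, -1.32 and -1.26 for ENSMFAG00000044843, and -0.96 and -0.76 for ENSMFAG00000035883.

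**Figure D1:**
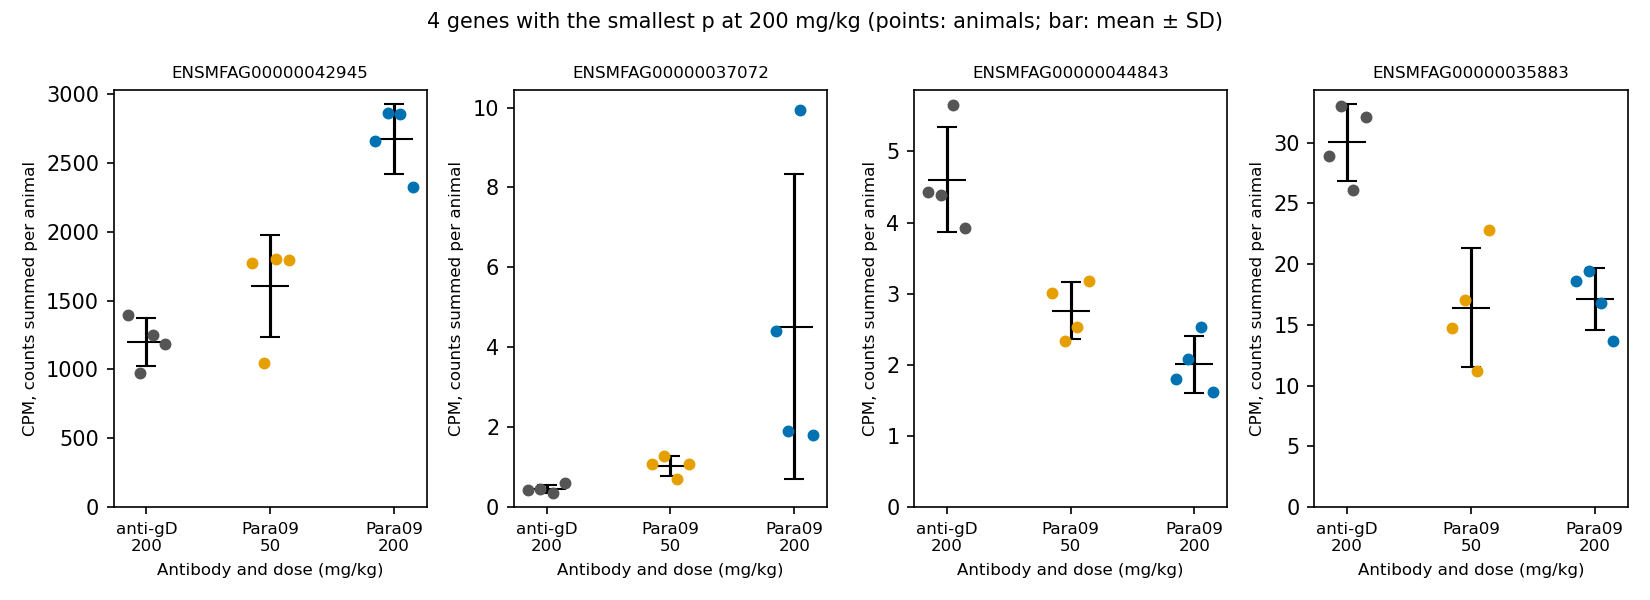
Library-size-scaled counts (CPM, linear axis from 0) of the 4 genes named at 200 mg/kg, with 1 point per animal, summed over its 3 libraries, and the mean ± SD of 4 animals as a bar. ENSMFAG00000042945 reached 2323 to 2861 CPM at 200 mg/kg and 974 to 1395 CPM with anti-gD.

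The 16 genes called at 200 mg/kg by the library-level model were 12 with higher and 4 with lower levels than with anti-gD. The log2 fold changes of the higher genes ran from 0.41 to 4.00, and those of the lower genes from -0.64 to -1.24. The 4.00 belongs to ENSMFAG00000043027, a gene near the floor with a mean log2 CPM of -2.07. Its log2 fold change was 3.18 in the edgeR fit on animal sums, 2.37 within letter B and 3.21 within the second series. The set included ENSMFAG00000042945 (adjusted p 0.00319 in this limma voom model, 2.83e-06 to 1 over 25 alternative fits), ENSMFAG00000037072 (0.0111, 3.8e-07 to 0.945) and ENSMFAG00000044843 (0.00477, 6.75e-06 to 1), but not ENSMFAG00000035883 (0.434, 0.0743 to 1). The direction was the same for 16 of 16 genes within letter B and within the second series, which are parts of the libraries that selected these genes. The number of calls depended on single animals: it was 35 without control animal 1502, 4 without control animal 1504 and 10 without animal 5503 at 200 mg/kg. Of its calls in simulated data with 200 changed genes 23.0% were false, and in 3 simulations without change it called 1, 2 and 3 genes.

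The comparison of Para09 at 50 mg/kg with anti-gD asked the same at the lower dose. ENSMFAG00000035883 stood at 16.4 CPM ± 4.87 at 50 mg/kg against 30.02 CPM ± 3.17 with anti-gD (SD, n = 4 animals), a log2 fold change of -0.87 (SE 0.19), and ENSMFAG00000044843 at 2.76 CPM ± 0.4 against 4.60 CPM ± 0.738, a log2 fold change of -0.73 (SE 0.19). ENSMFAG00000037072 stood at 1.03 CPM ± 0.242, with a log2 fold change of 1.16 (SE 0.50). ENSMFAG00000042945 stood at 1604 CPM ± 369, with a log2 fold change of 0.42 (SE 0.17), and its animals overlapped those given anti-gD (exact two-sided permutation p = 0.114). The edgeR test called 0 of 17360 genes, with a lowest adjusted p of 0.857. At an unadjusted p under 0.05 there were 996 genes, where evenly spread p-values give 868 with no gene changed. Other splits of the same animals gave a median of 512, and 12 of 35 splits, the real one included, gave as many. For the real groups the count was 566 without animal 4501 and 561 without animal 4503, up to 1490 without animal 4504. Over the alternatives other than leaving out 1 animal it ran from 191 to 1840, the highest within the second series alone. DESeq2 called 10 genes, 4 higher and 6 lower, and the library-level limma voom model called 0. Within letter B and within the second series edgeR called 0 genes each.

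The 2 doses were compared directly to ask whether the levels differ with dose. ENSMFAG00000042945 was higher at 200 than at 50 mg/kg by a log2 fold change of 0.74 (SE 0.17) and ENSMFAG00000037072 by 2.13 (SE 0.49), or 1.38 (SE 0.348) without animal 5503, without overlap of the animals for either gene (exact two-sided permutation p = 0.0286, the smallest possible). Both genes were picked for a small p at 200 mg/kg against anti-gD. The same 200 mg/kg animals enter here, so this arrangement is no independent evidence of a dose difference. ENSMFAG00000044843 differed by -0.46 (SE 0.19) and ENSMFAG00000035883 by 0.06 (SE 0.19), with overlapping animals for both, and the latter turned to -0.09 without animal 4503 and to -0.02 without animal 5502. None passed the edgeR test across genes, in which the lowest adjusted p was 0.961 and 0 of 17360 genes were called. At an unadjusted p under 0.05 there were 441 genes, where evenly spread p-values give 868 with no gene changed. Other splits of the same animals gave a median of 316, and 14 of 35 splits, the real one included, gave as many. For the real groups the count was 260 without animal 5501, and 140 to 831 over the alternatives other than leaving out 1 animal. DESeq2 called 1 gene, and the library-level limma voom model called 0. Over all 3 groups edgeR called 0 genes, with 675 at an unadjusted p under 0.05, against 868 from evenly spread p-values. Other splits of the same animals gave a median of 475, and 35 of 100 drawn splits, the real one included, gave as many. For the real groups the count ran from 223 to 1673 over those alternatives, the highest within the second series alone. DESeq2 called 27 genes and the limma voom model 16. Both within-series edgeR fits called 0 genes for the direct comparison and for the 3 groups.

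Of the 16 genes of the library-level model, 16 had the same direction at 50 mg/kg as at 200 mg/kg, and for 14 the change at 50 mg/kg was the smaller. Their median log2 fold change in the called direction was 1.05 at 200 mg/kg and 0.43 at 50 mg/kg, and 6 had an unadjusted p under 0.05 at 50 mg/kg. The genes were selected at 200 mg/kg, which enlarges that value, and both doses share the control animals, which favours a common direction. In 20 simulations of unchanged groups, which treat genes as independent, the 16 genes of smallest p at 200 mg/kg had the same direction at 50 mg/kg for a mean of 15 genes (14 to 16) and the same direction with a smaller change for a mean of 14 (12 to 16). Their median log2 fold change was 0.725 on average (0.467 to 0.908) at 200 mg/kg and 0.369 (0.25 to 0.507) at 50 mg/kg, so the common direction and the smaller change at 50 mg/kg are no more than unchanged groups gave. The observed median of 1.05 at 200 mg/kg was reached in 0 of the 20 simulations. That value does not exclude a chance arrangement of the animals.

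**Figure D2:**
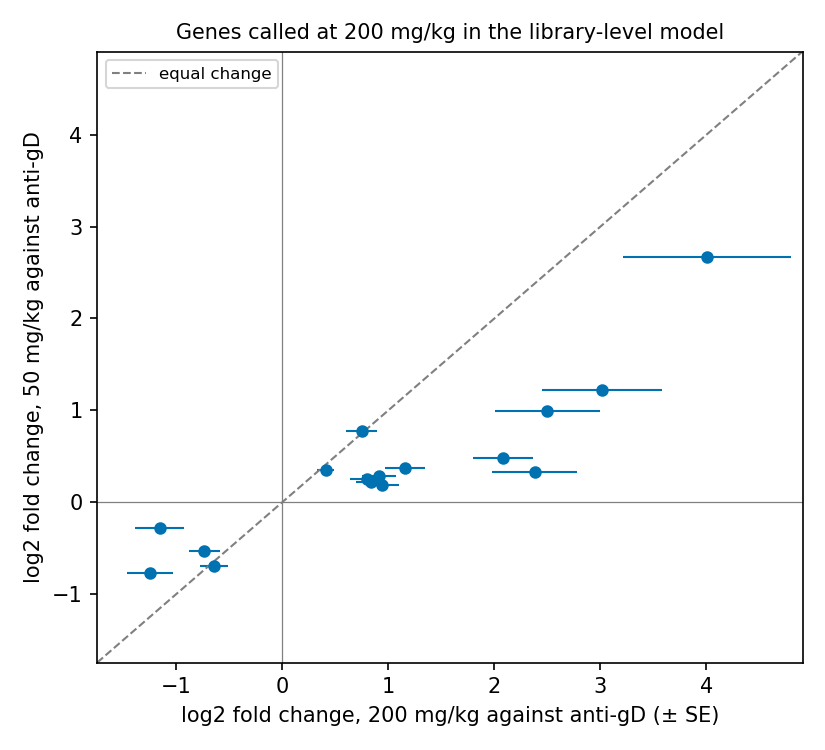
Log2 fold change against anti-gD at 200 mg/kg (horizontal axis, bars show the SE) and at 50 mg/kg (vertical axis) for the 16 genes called at 200 mg/kg by the library-level model. The dashed line marks equal change, and for 14 of the 16 genes the fold change at 50 mg/kg was the smaller, as for a mean of 14 in simulated unchanged groups.

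Across 14643 genes with a mean CPM of at least 1, the fold changes of the 2 doses against anti-gD correlated with r = 0.437 (covariance 0.0295), a correlation across genes, which are not independent replicates. Simulated unchanged groups against the same controls gave a mean r of 0.502 (highest 0.525, covariance 0.0361). With the controls split into separate pairs of animals for each dose, r averaged -0.14 over 6 splits (-0.432 to 0.202). On series-adjusted animal means r was 0.631 (covariance 0.0338) against a mean of 0.503 (highest 0.529, covariance 0.0235) in 50 simulations, which treat genes as independent and so understate the spread of r, and it was 0.0949 with split controls (0.0178 to 0.23). At an unadjusted p under 0.01, 24 genes were shared between the doses in the edgeR fit, 6 higher and 18 lower, where independent lists would share 0.24 and 0.277. Simulated unchanged groups shared 24.9 genes on average, and at most 33. In the library-level limma voom model, which adjusts for series, 60 genes were shared, 26 higher and 34 lower, where independent lists would share 0.889 and 1.49 and simulated unchanged groups shared a mean of 53.4 (42 to 67 in 20 simulations).

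The largest share of the variation between libraries followed the series of sample identifiers. The first principal component held 50.9% of the variance, and scores of the first series (-111 to -11.7) did not overlap those of the second (19.97 to 69.4). With terms entered in the order series, letter, group and animal, series accounted for 44.8% of the variation in log2 CPM. Animals within groups accounted for 23.5%, libraries within animals for 23.1%, treatment groups for 5.31% and letters for 3.35%. In 10 of the 12 animals the series parts letter B from letters A and C, so variation that series and letter share is credited to series. Per degree of freedom, groups accounted for 2.65% and animals within groups for 2.61%, so groups differed by about as much as animals of the same group did. In the library-level limma voom model 4499 genes differed between the series at an adjusted p under 0.05, 2489 higher and 2010 lower in the second. Between letters 0 genes differed (1005 at an unadjusted p under 0.05, where chance gives 796). In that model, telling letter B from letters A and C apart from series rests on the 4 first-series libraries with letters A and C. After the series difference was removed, the most similar library came from the same animal for 29 of the 36 libraries, where 2.06 would be found by chance.

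**Figure D3:**
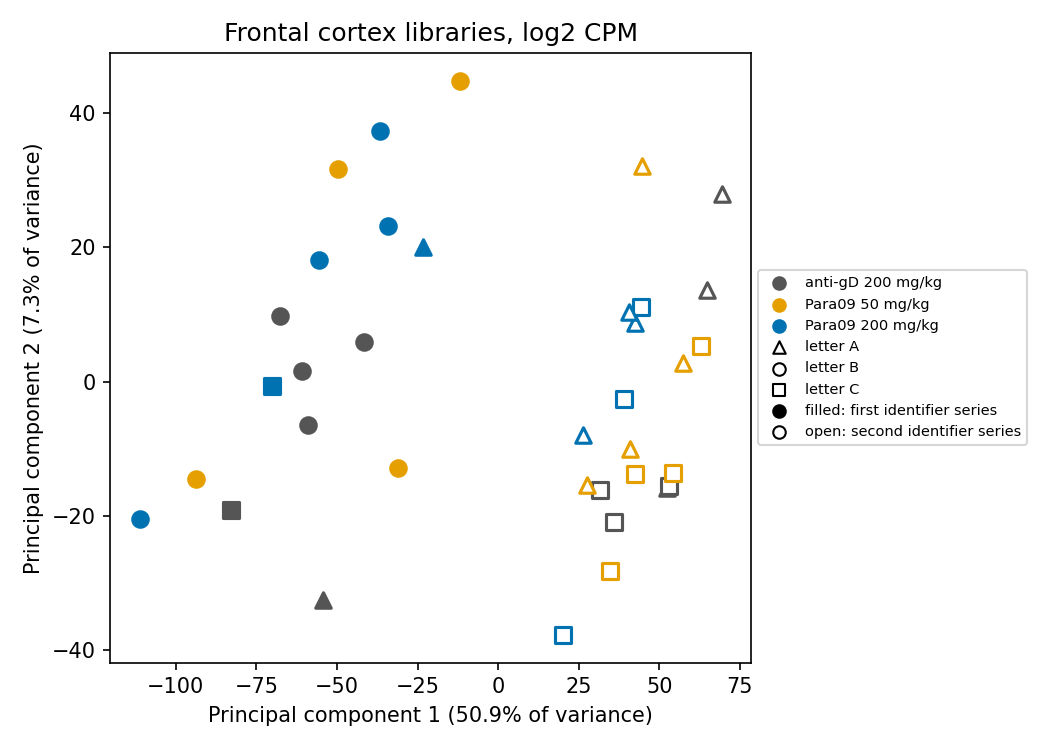
Principal components 1 and 2 of log2 CPM for the 36 libraries, coloured by treatment group, with the shape giving the letter and filled symbols marking the first series. All first-series libraries lie at -11.7 or below on component 1, and all second-series libraries at 19.97 or above.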

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

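The tests of the letter, of genes read in a single series and of fold changes within series were chosen only after the result was seen. Of 30 groups of 4 values examined for a value far from the rest, 5 had one, and chance gives about 1 in 20 groups.

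On principal component 1 of the animal sums, control animal 1504 scored 91.77 (next control -15.7) and animal 5501 at 200 mg/kg scored 89.81 (next -9.675), and these are the 2 animals with all libraries in the first series. The letter is argued against as the cause of the split between series, since the 4 first-series libraries with letters A and C scored -23.4 or lower against 19.97 or higher in the second series. Depth is argued against, since a gap of 24.8 remained after thinning to 15 M counts (31.7 before). Gene length is argued against, since 88.5% of 9860 genes differing between series within animals still did so after the length trend was removed. That model held no letter term, so its 9860 genes include differences between letter B and letters A and C, unlike the 4499 of the library-level model. In addition, among genes with a mean of at least 1 CPM in the series with counts, 13 had counts in every second-series library and 0 in the first series, and 8 the reverse. Counting error at low expression is argued against, since 0 of 100 random splits of the libraries into 16 and 20 gave as many such genes (highest 1), and so is the letter, since the 14 genes without counts in letter B had, in the 4 first-series libraries with letters A and C, a median of 0 times their second-series level (highest 0.00681). Both series list the same genes with the same exonic widths, which argues against a different gene list in the deposited tables. It does not show that reads of both series were aligned and counted with the same settings, which are not given and were not tested. A difference in library preparation may underlie the split and was not tested, and the design names no biological explanation.

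The 16 genes of the library-level model at 200 mg/kg did not rest on library 5501B, as 16 remained called without it. A difference between identifier series cannot act in a fit that holds a single series. In such fits the median log2 fold change of these 16 genes was at least 0.948 within each series, against 1.05 combined. These fits use parts of the libraries that selected the genes, and the selecting model held series as a covariate. A similar median was therefore favoured in advance, and it does not decide whether a series difference contributed. In 2 of 35 splits of the 8 animals, the real split and 1 other, as many genes were called as in the real split (17 with the correlation estimated on 1 in 5 genes, highest other split 22), so chance cannot be excluded. A response to Para09 may underlie some of these genes, and it stays a hypothesis because a chance arrangement of the animals stays open.

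Library 5501B, from 200 mg/kg, detected 15779 genes where the nearest letter B library of its group detected 18073. Depth is argued against, since 15676 genes were detected after thinning against at least 17881 in every other library, and so is a wrong label, since it correlated at 0.492 with the other libraries of animal 5501 and at most at 0.178 with another animal over 500 genes that differ between animals. Amplification of few distinct molecules may account for it: genes expected at 1 to 5 reads that were detected had a mean of 12.6 reads, against at most 7.25 in the other libraries, and 83.5% of such genes had none, against at most 52.7%. No biological explanation was tested.

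Animal 4504 at 50 mg/kg held 80.33 M counts, against 65.26 M in the next of its group. At 50 mg/kg ENSMFAG00000042945 stood at 1050 CPM in animal 4502, against 1773 CPM in the next lowest.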

How the results depend on the processing

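The count of 0 called genes held in 23 of 25 alternative fits at 200 mg/kg against anti-gD, 24 of 25 at 50 mg/kg, 24 of 25 for 200 against 50 mg/kg and 26 of 28 for the 3 groups, including every fit without 1 animal. The exceptions were DESeq2, with 14, 10, 1 and 27 genes in that order, and the library-level model, with 16 genes at 200 mg/kg and 16 for the 3 groups; the cause was not tested. DESeq2 and the library-level model shared 9 genes at 200 mg/kg. The calls of the library-level model ranged from 4 to 35 when 1 animal was left out: 35 without control 1502 (13 of the 16 genes shared), 4 without control 1504 (4 shared) and 10 without 5503 at 200 mg/kg (9 shared). It called 22 genes without library 5501B, 23 without a low-count filter, 16 at a mean CPM of at least 1 and 17 without the letter, sharing 16, 16, 15 and 16 of the 16 genes. Against anti-gD at 200 mg/kg each of the 4 named genes kept its direction in 25 of 25 fits. These fits reuse the animals on which the genes were picked, whose groups did not overlap, so a change of sign was unlikely beforehand. The shared genes of the 2 doses numbered 0 at an adjusted p under 0.05 and 24 at an unadjusted p under 0.01, as a looser threshold admits more genes. At that looser threshold the library-level model gave 60, a change of model as well; its part was not tested. The correlation of the doses turned from 0.437 to -0.14 with split controls. Simulated unchanged groups against the same 4 controls gave a mean r of 0.502, so sharing the controls alone can give the positive value. Each split put control animal 1504, with all libraries in the first series, in the control pair of a single dose. On series-adjusted animal means the correlation was 0.631, and 0.0949 with split controls (0.0178 to 0.23), without a change of sign. The negative mean was thus not seen once the series difference was removed. Those means also give libraries equal weight, and the 2 changes were not tested apart. The share of variation between series was 44.8% with a prior count of 2 and 45.8% with 0.5. The planned tests of gene lists, their alternatives and list levels per animal were not run, because the identifiers are not paired with names. No paired analysis was possible because the groups hold different animals. With 4 animals per group, most 1.5-fold changes were missed in simulation, so a count of 0 does not show absence of change.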

Other observations

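The counts of called genes on animal sums were set against other splits of the animals. The real splits called 0 genes, so every split necessarily gave as many, namely 35 of 35 at 200 mg/kg against anti-gD, 35 of 35 at 50 mg/kg, 35 of 35 for 200 against 50 mg/kg and 100 of 100 drawn splits for the 3 groups. These counts say nothing about chance, and the highest other splits called 1, 1, 0 and 1 genes. At an unadjusted p under 0.05 the real split of 200 mg/kg against anti-gD gave 691 genes, the other splits gave a median of 711.5, and 19 of the 35 splits gave as many. The 15 splits that put animals 1504 and 5501 on the same side gave 744 to 3048 genes, and these 2 animals have all libraries in the first series. The 20 splits that part them, the real split included, gave 216 to 922 genes, and 4 of these 20 gave as many as the real split, itself included. As many genes at an unadjusted p under 0.05 as in the real split were found in 12 of 35 splits at 50 mg/kg against anti-gD. For 200 against 50 mg/kg this held in 14 of 35 splits, and for the 3 groups in 35 of 100 drawn splits. The real split is included in each count. Within the first and within the second series edgeR called 0 genes.

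Of the 21 genes with counts in a single series and a mean of at least 1 CPM there, mean levels in that series ran from 1.01 to 82.7 CPM. In all, 790 genes with a mean of at least 1 CPM, the 13 above included, were higher in each second-series library than in any first-series library, and 57, the 8 above included, were higher in each first-series library.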
